A study of Homo sapiens with 6 samples.

How the data were processed

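Gene expression was measured by paired-end RNA-seq, run per the labels' protocols on an Illumina NovaSeq instrument, in 6 libraries of SW480 cells. Per the labels, RNA was collected in Trizol and each group had 3 biological replicates, so the p-values of single genes measure the spread between cultures of a cell line. If the cultures of a group came from 1 cell population, these p-values cannot separate HNF4A from other differences between the populations. Samples were grouped by the labelled genotype, 3 as control and 3 as HNF4A overexpression, and the replicate numbers 1 to 3 come from the sample titles. The columns of the deposited table were matched to samples by their names, and no column of per-sample values was left unused.

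The authors deposited 1 table of FPKM values, which are fragment counts scaled by transcript length and library total, for 60694 rows, named by gene symbol, beside their own group means, a fold change and a p-value. The submitters' processing notes name FastQC, Bowtie, Bowtie2, TopHat, TopHat2, Cufflinks and the genome build hg38, with no version, role or order. The annotation release, the strandedness of the libraries and the settings of these tools are not given in the sources used here. In the authors' deposited table the fold change is the ratio of the mean FPKM values. Its p-value matched an equal-variance Student test on the unlogged FPKM to within 0.1 percent in 32096 of the 32110 rows that hold a p, and it is not adjusted for multiple testing. The table holds 59332 distinct names. Of these, 215 stand on more than 1 row, 1577 rows in all, and 14 names had been turned into dates. All 6 libraries were at 0 in 28562 rows.

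FPKM values keep no read counts, so the absolute depth of each library is unknown, and no counting interval or detection floor was computed. Each library held 360 to 386 values above 0 but under 0.0001, lower than whole fragments give at usual depths and transcript lengths, so such values are probably model estimates. The most frequent ratio between libraries among genes under 0.05 FPKM gave a rough relative depth. Set against control replicate 1, it was 0.945 and 1.25 for control replicates 2 and 3 and 0.925, 0.907 and 0.869 for HNF4A overexpression replicates 1 to 3. Between 28.3 and 32.5 percent of the low genes lay within 0.1 log2 of that ratio. FPKM also depends on the total of each library and on the assumed transcript lengths, so a change in transcript usage can move a gene's value.

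Values were analysed as log2(FPKM + 1) in R 4.3.3 with limma 3.58.1 (lmFit and eBayes with a mean-variance trend, group as the only term). A log2 change on this scale understates the change of genes near or under 1 FPKM. Genes with an FPKM of at least 1 in at least 3 of the 6 libraries were tested, 14126 in all, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. HNF4A was also tested with an exact two-sided permutation test. Where a symbol stood on several rows, the row with the highest mean FPKM was used. Standard deviations are between the 3 libraries of a group, on the FPKM scale.

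The groups, the test, its alternatives, the rule for named genes and 29 gene lists were fixed before the data were examined. Of the 737 listed genes 736 were in the table, some through RefSeq synonyms. The 25 lists with at least 5 tested members were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera was repeated with an estimated correlation, a version that also has fewer degrees of freedom. The fry test asked whether a list's members moved on balance in 1 direction. Camera at the preset correlation, and the later intervals and shuffles over genes, treat genes and not cultures as the units. The rule named HNF4A, the 12 genes higher and the 12 lower with the largest change among genes past the threshold whose groups did not overlap, and up to 4 passing members of each list. For lists with no passing member it named the 2 with the highest mean. It also named all passing members of the HNF4A target, Wnt and intestinal transcription factor lists and 10 single genes whatever their value. Some genes that the rule named are not reported here. After the largest changes had been seen, clone-based names and names turned into dates were taken not to be gene symbols under this rule.

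Data were simulated for the same 14126 genes with the variances as moderated by limma, which lie closer to the mean-variance trend than the observed ones. There the test recovered 68 percent of genes changed by 0.5 log2 and 97 percent of those changed by 1 log2. Of all calls 5.17 percent were false. These rates may not hold for the observed spread. In a separate simulation 1 list shifted by 0.4 log2 was found and 0 of the other lists were called. Both simulations drew the noise of each gene separately, without correlation between genes. In the real data the estimated correlation reached 0.907, in the histone list. The simulations therefore do not give the rate of false calls among correlated genes or lists. Coordinates and overlaps between genes came from GENCODE release 29 on GRCh38, the assembly also called hg38, matched by gene name. That release may differ from the authors' annotation. Windows and neighbours along the genome, depth and figures were computed in Python 3.11.15 with pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

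The alternatives were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 FPKM, scaling to TPM, median-of-ratios scaling, quantile normalization, limma without trend or with robust variances, the replicate number as a block, a minimum log2 change of 1, an adjusted p under 0.01, and leaving out each library in turn. Leave-one-out fits used the genes that pass the filter over all 6 libraries. This was settled after the counts from fits with the filter reapplied to the remaining libraries had been seen, and the counts of both versions are reported.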

Results

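RNA-seq profiles of SW480, an established human colorectal cancer cell line, were compared between 3 control libraries and 3 libraries of cells overexpressing HNF4A. The sample titles read lenti for control and lenti-HNF4a for overexpression. The control was therefore probably SW480 with a lentiviral vector lacking HNF4A, and not unmodified SW480. HNF4A is a nuclear receptor that acts as a transcription factor in liver and intestinal epithelium. The series title names it in connection with the Wnt/beta-catenin pathway and colorectal carcinogenesis, and the design implies 1 comparison, of gene expression with and without the added HNF4A. The values are FPKM, so read totals are unknown. FPKM summed to between 615594 and 652879 per library, and 13905 to 14213 rows per library reached 1 FPKM. Across the tested genes, which are not independent replicates, log2 values correlated at 0.9895 to 0.9919 within groups and at 0.9839 to 0.9875 between groups. The first principal component held 39.9 percent of the variance and separated the groups.

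HNF4A itself, on chromosome 20 from 44355700 to 44434596 (GRCh38, plus strand), was measured at 7.62 ± 1.12 FPKM in control (SD, n = 3) and 905 ± 216 FPKM in HNF4A overexpression (SD, n = 3), a 119-fold difference. The control libraries held 8.81, 6.57 and 7.47 FPKM and the overexpression libraries 1143, 720.6 and 852 FPKM, so every library matched its label. The log2 change was 6.70 with a standard error of 0.16 (limma adjusted p = 1.01e-06). The exact two-sided permutation test gave p = 0.1, the smallest that the 20 assignments of 3 against 3 allow. The authors' deposited table gives a fold change of 119 and an unadjusted p of 0.00199 for this gene. A gene-level value does not separate transcripts of the introduced gene from those of the endogenous gene.

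The rankings by log2 change in this and the next paragraph leave out clone-based names and names turned into dates. After HNF4A, the largest rise by log2 change was that of S100A9, a calcium-binding protein of myeloid cells and inflamed epithelia, from 0.14 ± 0.0916 to 4.96 ± 0.572 FPKM (log2 change 2.39, adjusted p = 1.83e-04). SLC7A7, a subunit of a cationic amino acid transporter, rose 3.95-fold from 24.7 ± 5.62 to 97.8 ± 5.73 FPKM (adjusted p = 6.16e-04). USH1C, which encodes the brush border scaffold harmonin, rose 4.21-fold from 4.19 ± 0.78 to 17.6 ± 3.0002 FPKM, and ABCB1, the drug efflux pump P-glycoprotein, rose 4.25-fold from 2.01 ± 0.45 to 8.54 ± 0.758 FPKM. Among the genes that fell, CXCR4, the receptor of the chemokine CXCL12, went from 47.0 ± 1.38 to 19.8 ± 3.46 FPKM (log2 change -1.22, adjusted p = 0.00137), and the translation elongation factor gene EEF1A2 from 81.1 ± 12.1 to 36.8 ± 4.44 FPKM (log2 change -1.11, adjusted p = 0.00191).

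The other genes with the largest rises had log2 changes of 1.98 for RASGRP2, 1.95 for AZGP1, 1.91 for PRAP1, 1.78 for IL32, 1.74 for CCL15, 1.63 for the complement gene C3 and 1.63 for PPP1R14D. CCL15 was listed at 0, 0.0656 and 4.72e-08 FPKM in the control libraries and at 3.53, 1.49 and 2.51 FPKM in the overexpression libraries, so no fold is given. The other genes with the largest falls had log2 changes of -1.59 for the keratin gene KRT6A, -1.40 for the potassium channel gene KCNJ4, -1.38 for the decoy receptor gene TNFRSF6B, -1.27 for SPANXB1, -1.20 for LYPD6B, -1.19 for AK5, -1.15 for CD52, -1.02 for PADI1, -1.0008 for FABP3 and -0.98 for RLBP1. All 12 rises, HNF4A included, and 8 of the 12 falls passed in each of the 6 fits that left out 1 library. The call of KRT6A was lost without any of the 3 controls or without HNF4A overexpression replicate 1 (adjusted p between 0.0669 and 0.116) and with the replicate number as a block (0.0571), and that of SPANXB1 without any library but HNF4A overexpression replicate 3 (adjusted p between 0.0668 and 0.0971). AK5 lost its call without HNF4A overexpression replicate 2 (adjusted p = 0.0604), and PADI1 without control replicate 2 (0.0724) or 3 (0.0720).

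In GENCODE 29, S100A9 lies on chromosome 1 from 153357854 to 153361027, SLC7A7 on chromosome 14 from 22773222 to 22829820, USH1C on chromosome 11 from 17493895 to 17544416, ABCB1 on chromosome 7 from 87503633 to 87713323, CXCR4 on chromosome 2 from 136114349 to 136118165 and EEF1A2 on chromosome 20 from 63488012 to 63499322. PRAP1, CCL15 and TNFRSF6B each overlap a readthrough gene on their own strand, C3 overlaps GPR108, and KRT6A and SPANXB1 have near-identical relatives, so their values may include shared fragments. Strand use in the counting is not stated, and HNF4A, PRAP1, IL32, CCL15, ABCB1, KCNJ4, TNFRSF6B, LYPD6B, AK5 and CD52 overlap annotated genes on the other strand.

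**Figure D1:**
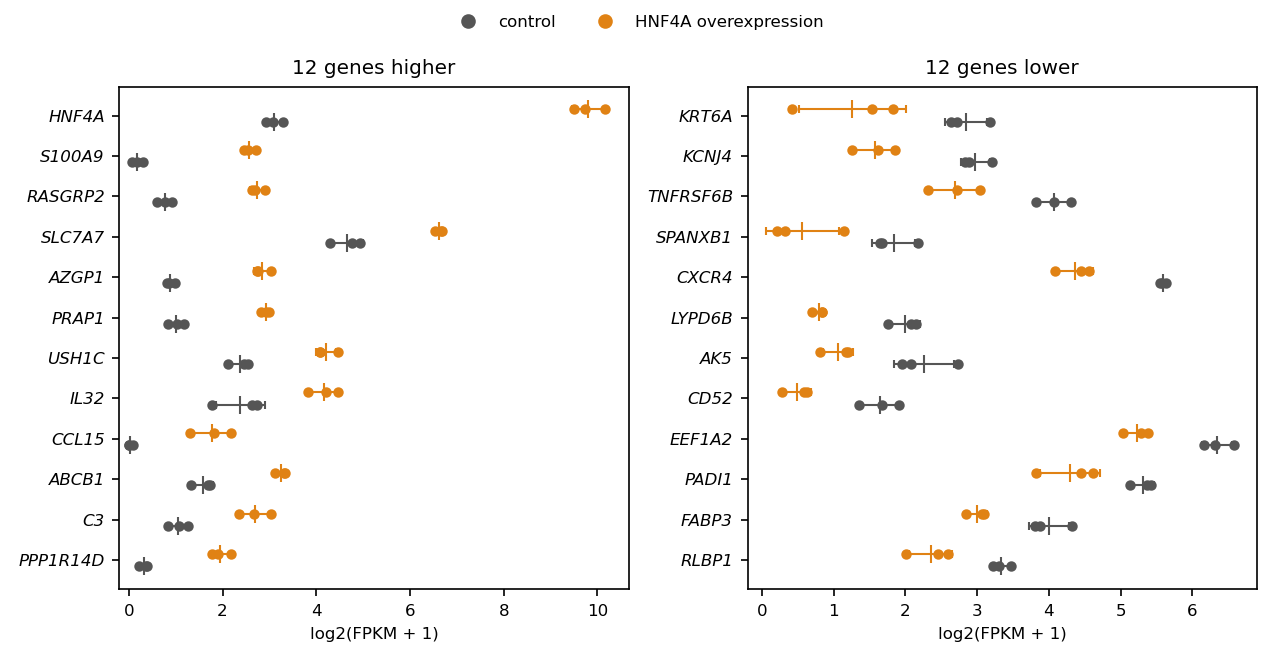
FPKM of the 12 genes with the largest rise (left) and the 12 with the largest fall (right), as log2(FPKM + 1) on the horizontal axis. Genes were ranked among those past the threshold, without clone-based names and names turned into dates. Each point is 1 library (grey, control, n = 3; orange, HNF4A overexpression, n = 3), vertical ticks are group means and bars are SD, and for each gene the points of the groups do not overlap.

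Over all 14126 tested genes, 480 were higher and 196 lower in HNF4A overexpression (limma with Benjamini-Hochberg adjustment). At an unadjusted p under 0.05 there were 2547 genes. Most changes were small, with a median log2 change of 0.56 among the higher and -0.46 among the lower genes, and 65 genes rose and 12 fell by at least 1 on the log2 scale. Median control FPKM was 7.01 for the higher and 21.7 for the lower genes. In all 676 genes the groups did not overlap, which was so for 23.8 percent of tested genes, against 10 percent by chance. Leaving out any 1 library left 274 to 307 higher and 87 to 160 lower genes, and 277 of the 676 (220 higher, 57 lower) were called in each of these 6 fits. Without the filter 201 genes passed as higher and 47 as lower, and 34 of the genes chosen by the naming rule lost their call. With the replicate number as a block, which the design does not name, 635 passed as higher and 400 as lower.

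**Figure D2:**
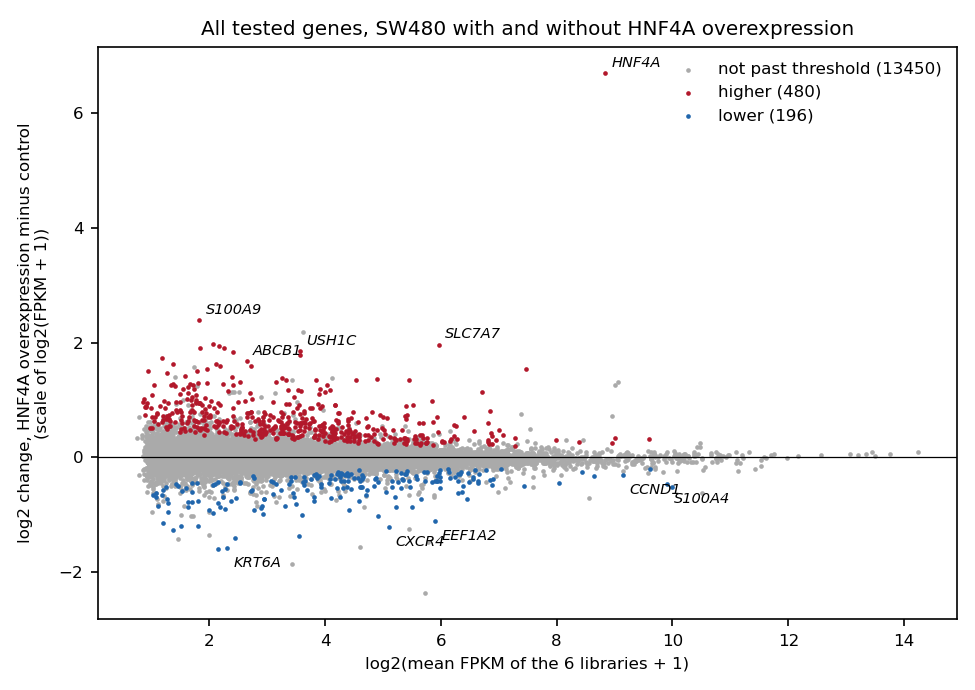
Log2 change of each of the 14126 tested genes (vertical axis, HNF4A overexpression minus control, scale of log2(FPKM + 1)) against the log2 of its mean FPKM over the 6 libraries plus 1. Red points are the 480 genes higher and blue points the 196 genes lower at an adjusted p under 0.05, grey points did not pass, and HNF4A stands apart at 6.70.

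Of 32 genes of enterocyte and colonocyte differentiation 9 were tested, of which 6 rose, 0 fell and 3 did not pass, also when adjusted over the list alone. The median log2 change of the tested members was 0.88 (camera adjusted p = 1.35e-07, adjusted p = 0.227 with an estimated correlation, fry adjusted p = 0.00710). The genes that rose were PRAP1, USH1C, the actin bundling genes VIL1 (12.1 ± 2.46 to 32.3 ± 4.36 FPKM, adjusted p = 0.00183) and ESPN (14.4 ± 0.13 to 19.2 ± 0.712 FPKM, adjusted p = 0.00734), the glucose transporter gene SLC5A1 (0.285 ± 0.0803 to 1.75 ± 0.349 FPKM, adjusted p = 0.00348) and the peptide transporter gene SLC15A1 (0.298 ± 0.0628 to 1.40 ± 0.22 FPKM, adjusted p = 0.00607). The other 23 members were under the filter, 14 of them below 0.1 FPKM in every library. All 18 goblet and other secretory markers were under the filter. The most abundant, LYZ and CHGA, averaged 0.446 and 0.416 FPKM in control and 0.833 and 0.482 FPKM in HNF4A overexpression.

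Of 44 HNF4A target genes known from liver and gut, 7 were expressed enough to be tested, and 31 of the other 37 were below 0.1 FPKM in every library. SERPINA1, the alpha-1-antitrypsin gene, rose from 79.5 ± 3.31 to 109 ± 5.598 FPKM (adjusted p = 0.00354) and ACOX2, a peroxisomal oxidase gene of bile acid synthesis, from 0.807 ± 0.259 to 1.73 ± 0.0616 FPKM (adjusted p = 0.0373). Among the leave-one-out fits ACOX2 passed only without control replicate 3 (0.0336), with adjusted p-values of 0.0990 to 0.109 in the others. Adjusted over the list alone 3 members rose, and 0 fell by either adjustment. The median log2 change was 0.26 (camera adjusted p = 0.0577, fry adjusted p = 0.00926). The camera value passed the threshold without control replicate 1 (0.0191), control replicate 3 (0.0388) or HNF4A overexpression replicate 2 (0.0407), with a range of 0.0191 to 0.4999 over the alternatives that gave a value. Of 20 hepatocyte-restricted genes only C3 passed the filter, and it rose from 1.10 ± 0.311 to 5.57 ± 1.52 FPKM.

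Among 11 tested intestinal and endodermal transcription factors 2 rose, 2 fell and 7 did not pass, and over the list alone 3 rose and 2 fell (camera adjusted p = 0.828). ELF3, an epithelial ETS factor, rose from 5.94 ± 0.738 to 10.97 ± 1.38 FPKM (adjusted p = 0.00606). KLF4 fell from 6.66 ± 0.523 to 4.98 ± 0.189 FPKM (adjusted p = 0.0472) and KLF5 from 39.7 ± 0.887 to 33.4 ± 0.54 FPKM (adjusted p = 0.0265). KLF4 (0.0817 to 0.133) and KLF5 (0.0611 to 0.0879) passed in 0 of the 6 leave-one-out fits. CDX2, a caudal-type homeobox factor of the intestine, was at 18.6 ± 2.73 and 25.05 ± 3.56 FPKM (adjusted p = 0.110, or 0.00873 with the replicate block).

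Wnt/beta-catenin target genes did not move together. Of 28 tested, 3 rose, 1 fell and 24 did not pass, and over the list alone 6 rose and 7 fell (median log2 change -0.03, camera adjusted p = 0.569). TCF7, a transcription factor of the pathway, rose from 25.1 ± 1.48 to 36.0 ± 3.56 FPKM (adjusted p = 0.0115), NOTUM, a secreted enzyme that inactivates Wnt ligands, from 18.3 ± 1.28 to 25.4 ± 1.01 FPKM (adjusted p = 0.00787), and TNFRSF19 from 9.49 ± 0.419 to 13.5 ± 1.26 FPKM (adjusted p = 0.0162). CCND1, which encodes cyclin D1, fell from 629 ± 34.7 to 509 ± 27.2 FPKM (adjusted p = 0.0267). Among the leave-one-out fits TNFRSF19 passed only without control replicate 3 or HNF4A overexpression replicate 2 (adjusted p of 0.0503 to 0.0609 in the others), and CCND1 only without HNF4A overexpression replicate 2 (0.0549 to 0.0813 in the others). MYC was at 75.3 ± 2.83 and 72.8 ± 1.20 FPKM (adjusted p = 0.685) and AXIN2 at 216 ± 2.20 and 208 ± 8.18 FPKM (adjusted p = 0.611). LGR5 averaged 0.0104 and 0.00811 FPKM and was not tested.

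**Figure D3:**
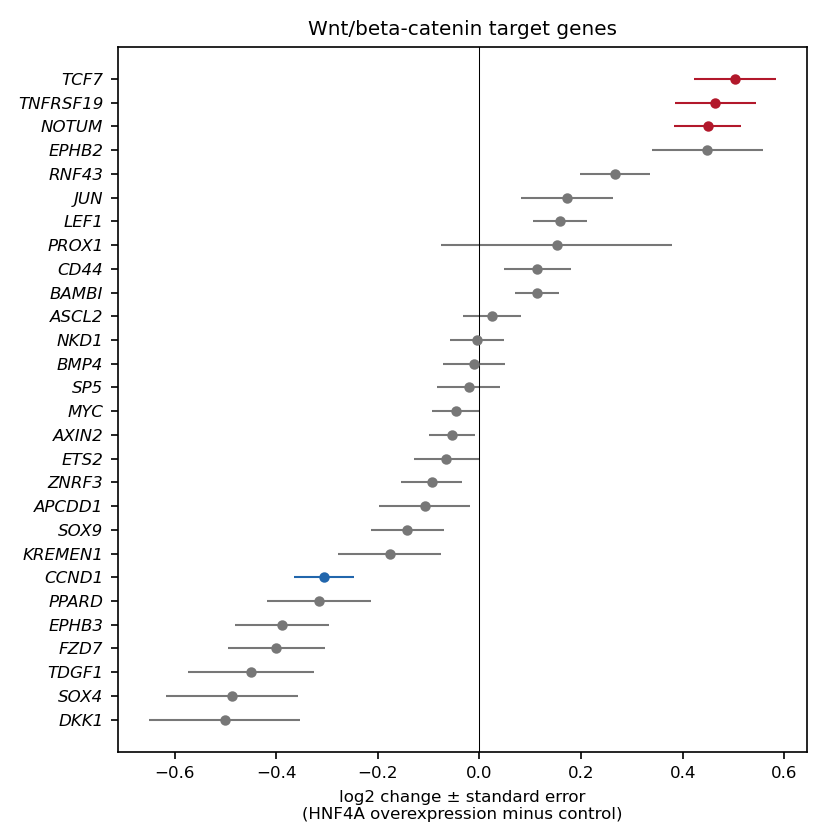
Log2 change (HNF4A overexpression minus control, scale of log2(FPKM + 1)) of the 28 tested Wnt/beta-catenin target genes, with bars for the standard error of the limma fit. TCF7, TNFRSF19 and NOTUM (red) passed as higher and CCND1 (blue) as lower, and the other 24 genes (grey) did not pass.

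Of 34 tested Wnt pathway components 3 rose and 3 fell, or 5 and 5 over the list alone (median log2 change -0.04, camera adjusted p = 0.436). WLS, the carrier that brings Wnt ligands to the cell surface, rose from 24.0 ± 0.526 to 33.7 ± 0.423 FPKM (adjusted p = 0.00176), and the ligand gene WNT11 from 3.84 ± 0.67 to 7.31 ± 0.927 FPKM (adjusted p = 0.0106). The co-receptor gene LRP5 rose from 24.9 ± 0.828 to 30.5 ± 1.35 FPKM (adjusted p = 0.0300). The receptor genes FZD1 (4.58 ± 0.0643 to 2.72 ± 0.347 FPKM, adjusted p = 0.0117) and FZD9 (2.58 ± 0.187 to 1.48 ± 0.149 FPKM, adjusted p = 0.0238) fell, as did PORCN, the acyltransferase of Wnt ligands (18.0 ± 0.464 to 14.3 ± 0.444 FPKM, adjusted p = 0.0206). FZD1 lost its call without control replicate 3 (adjusted p = 0.0512). LRP5 and PORCN passed only without HNF4A overexpression replicate 1 (up to 0.103 and 0.0710 in the other leave-one-out fits), and FZD9 only without HNF4A overexpression replicate 3 (up to 0.0812). CTNNB1, the beta-catenin gene, was at 392 ± 20.7 and 386 ± 4.73 FPKM (adjusted p = 0.896).

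Of 39 xenobiotic metabolism genes 26 were under the filter, 15 of them below 0.1 FPKM in every library. Of the 13 tested 3 were higher, 0 lower and 10 did not pass, with 5 higher over the list alone. The tested members passed as higher by camera and fry (median log2 change 0.34, camera adjusted p = 0.00103, adjusted p = 0.227 with an estimated correlation, fry adjusted p = 0.00885). Besides ABCB1, the sulfotransferase gene SULT2B1 rose from 1.25 ± 0.224 to 5.82 ± 0.929 FPKM (adjusted p = 7.85e-04) and the glutathione transferase gene GSTP1 from 453 ± 10.9 to 576 ± 65.7 FPKM (adjusted p = 0.0478), the latter among the leave-one-out fits only without HNF4A overexpression replicate 2 (0.0674 to 0.130 in the others). In fatty acid oxidation 2 of 21 tested genes rose, by both adjustments (camera adjusted p = 0.215, or 0.0309 without control replicate 2, with a range of 0.0309 to 0.865 over the alternatives run for the list). ACAA1, a peroxisomal thiolase gene, rose from 30.5 ± 0.643 to 50.9 ± 3.74 FPKM (adjusted p = 9.63e-04), and ACSL5, an acyl-CoA synthetase gene, from 8.52 ± 0.727 to 13.4 ± 0.969 FPKM (adjusted p = 0.00606). In cholesterol synthesis 1 of 24 tested genes rose, 1 fell and 22 did not pass, also over the list alone (camera adjusted p = 0.215). HMGCS1, a synthase gene of the pathway, rose from 7.83 ± 0.404 to 10.7 ± 0.352 FPKM (adjusted p = 0.0146). HMGCS1 lost its call without control replicate 1, control replicate 2 or HNF4A overexpression replicate 2 (adjusted p of 0.0510 to 0.0595). None of 18 tested fatty acid synthesis genes passed by either adjustment (camera adjusted p = 0.877), and the list's camera direction was down while its median and mean log2 change were both 0.02. ACLY was at 69.4 ± 3.53 and 67.0 ± 2.56 FPKM and AGPAT2 at 74.3 ± 3.31 and 64.4 ± 2.94 FPKM.

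Of 27 tested epithelial junction genes 2 rose and 0 fell, and over the list alone 4 rose and 1 fell (camera adjusted p = 0.828). CDH1, the E-cadherin gene, rose from 12.02 ± 0.939 to 17.7 ± 0.554 FPKM (adjusted p = 0.00524), and the tight junction gene TJP3 from 2.43 ± 0.497 to 4.29 ± 0.626 FPKM (adjusted p = 0.0399), among the leave-one-out fits only without control replicate 2 or HNF4A overexpression replicate 3 (0.0939 to 0.126 in the others). Of 21 mesenchymal genes 3 rose and 1 fell, or 4 and 4 over the list alone. SNAI2, a repressor of E-cadherin transcription, rose from 1.33 ± 0.0475 to 3.48 ± 0.386 FPKM (adjusted p = 0.00209), ACTA2 from 6.82 ± 0.734 to 10.5 ± 0.363 FPKM (adjusted p = 0.00839) and L1CAM from 64.3 ± 0.98 to 83.5 ± 1.38 FPKM (adjusted p = 0.00271). S100A4 fell from 1116 ± 61.4 to 810.3 ± 75.6 FPKM (adjusted p = 0.0115). This list went down by its median log2 change of -0.10 and by camera (adjusted p = 0.569) but up by fry (adjusted p = 0.645). VIM, the vimentin gene, was at 340.0 ± 24.5 and 297 ± 26.8 FPKM (adjusted p = 0.225). In TGF-beta and BMP signalling 1 of 15 tested genes rose and 0 fell, or 1 and 1 over the list alone (camera adjusted p = 0.569). It was SMAD3 (14.8 ± 0.436 to 18.6 ± 0.609 FPKM, adjusted p = 0.0222), which among the leave-one-out fits passed only without HNF4A overexpression replicate 2 (0.0521 to 0.0821 in the others).

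Of 17 tested interferon response genes 4 rose and 0 fell, and over the list alone 5 rose and 2 fell (camera adjusted p = 0.1502, fry adjusted p = 0.00926). OAS1 rose from 2.10 ± 0.353 to 5.90 ± 0.561 FPKM (adjusted p = 0.00161), MX2 from 1.44 ± 0.167 to 3.68 ± 0.0368 FPKM (adjusted p = 0.00176), IFI6 from 19.0 ± 2.36 to 31.0 ± 1.86 FPKM (adjusted p = 0.00436) and MX1 from 5.11 ± 0.477 to 7.35 ± 0.269 FPKM (adjusted p = 0.0220, and 0.0504 to 0.0786 without any library but control replicate 3). None of 9 tested NF-kB and inflammatory genes passed, and 1 rose over the list alone (camera adjusted p = 0.921). SAA1 was at 172 ± 19.0 and 165 ± 30.4 FPKM and SAA2 at 35.9 ± 2.73 and 34.6 ± 5.52 FPKM.

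Of 18 tested immediate early and stress genes 3 fell and 1 rose, or 5 and 1 over the list alone. The list passed as lower by camera but not by fry (median log2 change -0.12, camera adjusted p = 0.00977, adjusted p = 0.647 with an estimated correlation, fry adjusted p = 0.366). In 3 of the 9 other splits of the libraries into 3 and 3 its camera adjusted p was smaller, at 0.00386, 0.00101 and 0.00648. The camera value was 0.0522 without HNF4A overexpression replicate 1, with a range of 2.98e-04 to 0.647 over the alternatives run for the list. IER3 fell from 202 ± 7.74 to 143 ± 11.1 FPKM (adjusted p = 0.00423), FOSL1, a subunit of the transcription factor AP-1, from 102 ± 7.19 to 74.8 ± 0.554 FPKM (adjusted p = 0.00453) and KLF2 from 9.51 ± 1.69 to 5.73 ± 0.587 FPKM (adjusted p = 0.0273, and 0.0529 to 0.0895 without any library but control replicate 1). The stress-induced transcription factor gene ATF3 rose from 7.02 ± 0.759 to 12.7 ± 0.471 FPKM (adjusted p = 0.00196). It was also the 1 gene of 22 tested in the unfolded protein response that rose, by both adjustments, with 0 lower (camera adjusted p = 0.668).

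In glycolysis 2 of 21 tested genes fell and 0 rose, or 3 and 0 over the list alone (camera adjusted p = 0.249). They were ENO2 (45.2 ± 1.21 to 36.7 ± 0.558 FPKM, adjusted p = 0.0116) and PKM (842 ± 7.05 to 727 ± 27.8 FPKM, adjusted p = 0.0413), the latter in 0 of the 6 leave-one-out fits (0.0541 to 0.127). In the hypoxia list 1 of 16 rose and 1 fell, or 3 and 3 over the list alone (camera adjusted p = 0.454). CA9 rose from 0.386 ± 0.216 to 1.31 ± 0.221 FPKM and NDRG1 fell from 46.1 ± 4.62 to 31.7 ± 4.38 FPKM. Among the leave-one-out fits CA9 passed only without control replicate 1 (up to 0.0923 in the others), and NDRG1 only without control replicate 2 or HNF4A overexpression replicate 3 (up to 0.0937). None of 19 tested p53 target and apoptosis genes passed by either adjustment (camera adjusted p = 0.676). Their median log2 change was 0.0075 and their mean -0.018, with camera down. BCL2L1 was at 165 ± 4.76 and 146 ± 4.80 FPKM and BAX at 104 ± 6.95 and 103 ± 9.93 FPKM.

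None of 34 proliferation genes passed by either adjustment (median log2 change -0.0081, camera adjusted p = 0.107). The camera value was 0.00272 without control replicate 3 and 0.00322 without HNF4A overexpression replicate 1, with a range of 0.00272 to 0.872 over the alternatives run for the list. MKI67, the Ki-67 gene, was at 46.3 ± 3.12 and 42.5 ± 3.10 FPKM (adjusted p = 0.441), UBE2C at 315 ± 16.6 and 283 ± 15.7 FPKM and MCM7 at 300 ± 16.2 and 292 ± 12.3 FPKM. Of 6 tested replication-dependent histone genes 0 passed over all genes and 5 fell over the list alone. The list passed as lower by camera but not by fry (median log2 change -0.54, camera adjusted p = 8.82e-04, adjusted p = 0.647 with an estimated correlation, fry adjusted p = 0.366). HIST1H2BK was at 465 ± 56.8 and 289 ± 72.1 FPKM (adjusted p = 0.0569, or 0.0234 without HNF4A overexpression replicate 3 and 0.00829 with the replicate block) and HIST1H1C at 163 ± 34.7 and 112 ± 27.5 FPKM (adjusted p = 0.195, or 0.0254 with the block). None of 66 cytosolic ribosomal protein genes (camera adjusted p = 0.610) and none of 36 nuclear genes of oxidative phosphorylation (0.283) passed by either adjustment. RPL10 was at 2394 ± 76.9 and 2370.3 ± 46.3 FPKM, RPL35 at 2324 ± 128 and 2386 ± 49.0 FPKM, ATP5F1B at 544 ± 9.60 and 527 ± 26.0 FPKM and COX6B1 at 490 ± 13.3 and 458 ± 8.95 FPKM. Of 15 mitochondrially encoded genes 1 rose and 0 fell by both adjustments (camera adjusted p = 0.1502), with values of 0.0376 without control replicate 1 and 0.0208 without HNF4A overexpression replicate 2 and a range of 0.0208 to 0.865 over the alternatives run for the list. It was the ribosomal RNA gene MT-RNR1 (689 ± 50.6 to 862 ± 58.7 FPKM, adjusted p = 0.0413), which passed in 0 of the 6 leave-one-out fits (0.0525 to 0.111). Mitochondrially encoded genes made up 15.6 to 18.0 percent of the FPKM sum in control and 15.6 to 19.6 percent in HNF4A overexpression libraries.

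Of the 16 leukocyte markers 5 were tested. Of these 2 rose and 1 fell, or 3 and 1 over the list alone (camera adjusted p = 0.1502, fry adjusted p = 0.00885). The lysosomal genes LAPTM5 (6.38 ± 0.712 to 15.5 ± 1.65 FPKM, adjusted p = 9.79e-04) and CD68 (0.582 ± 0.196 to 2.74 ± 0.147 FPKM, adjusted p = 0.00161) rose, and CD52, a lymphocyte surface glycoprotein gene, fell from 2.17 ± 0.617 to 0.418 ± 0.175 FPKM (adjusted p = 0.00810). The other 11 leukocyte markers were under the filter. Of the fibroblast markers 2 of 15 were tested and 0 passed, with COL6A1 at 20.1 ± 2.91 and 15.5 ± 3.44 FPKM (adjusted p = 0.258, or 0.0341 with the replicate block) and COL1A1 at 2.18 ± 0.331 and 3.06 ± 0.228 FPKM. Over that list alone 1 rose and 1 fell. Of the endothelial markers 2 of 12 were tested, and 1 rose, or 2 over the list alone. It was ENG (1.01 ± 0.0891 to 1.83 ± 0.109 FPKM, adjusted p = 0.0337), which passed in 0 of the 6 leave-one-out fits (0.0701 to 0.111).

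**Figure D4:**
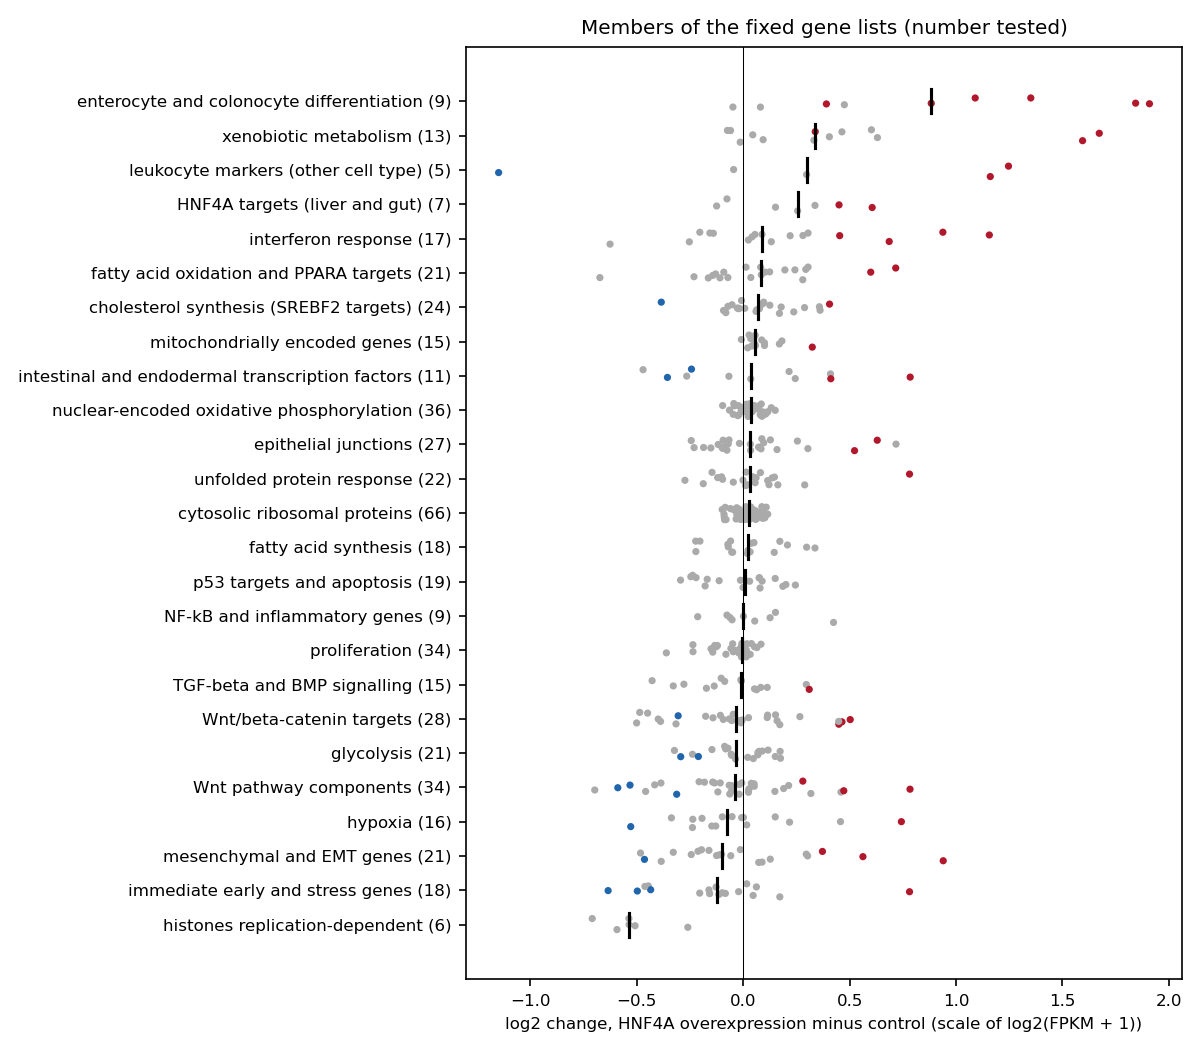
Log2 change (horizontal axis, HNF4A overexpression minus control, scale of log2(FPKM + 1)) of the tested members of the 25 gene lists with at least 5 tested members, with the number tested in brackets. Red and blue points are members higher and lower at an adjusted p under 0.05 over all genes, grey points did not pass, and black bars are medians, from 0.88 in the enterocyte list to -0.54 in the histone list.

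In the authors' deposited table, 2274 of the tested genes have an unadjusted p under 0.05, 1358 of them higher and 916 lower in HNF4A overexpression, and this holds for 675 of the 676 genes called here. After Benjamini-Hochberg adjustment of the authors' p over the tested genes 34 passed. Among the 100 smallest p-values that the authors deposited, 40 belong to rows whose highest library was under 1 FPKM, and 26 to rows with 1 group listed at 0 throughout.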

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

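How the filter enters the leave-one-out fits was settled after the data were seen, and all other alternatives before. HNF4A stayed past the threshold under every alternative, with a log2 change of 6.52 to 6.86. Against 480 higher and 196 lower genes, no filter gave 201 and 47, a minimum log2 change of 1 gave 65 and 12, and an adjusted p under 0.01 gave 193 and 47. Leaving out a library gave 274 to 307 higher and 87 to 160 lower genes, from fewer samples. With the filter reapplied these were, without control replicates 1 to 3, 298, 293 and 277 higher and 95, 91 and 83 lower, and without HNF4A overexpression replicates 1 to 3, 235, 271 and 256 higher and 83, 96 and 154 lower. Other pseudocounts, the filter of 5 FPKM, the scalings and the limma settings left both counts within 1.5 times.

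Same-numbered libraries deviated together with correlations of 0.135, 0.093 and 0.149 across genes. As 1 was not over 0.1, the numbers were not taken to pair the samples. Every library correlated best with its own number, which is a hint from the data and not from the design. The replicate block gave 635 higher and 400 lower genes.

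The HNF4A target list (0.0577) reached a camera adjusted p of 0.0446 without a filter and 0.0477 after median-of-ratios scaling, of 0.0191 to 0.213 when a library was left out, and at most 0.4999 elsewhere. With the filter of 5 FPKM this list and the leukocyte list gave no value, as fewer than 5 members were left. The Wnt target list stayed over the threshold, between 0.385 and 0.891. The 4 other lists past the threshold became 0 with an estimated correlation. Directions of lists far from the threshold turned for epithelial junctions (0.855) and NF-kB genes (0.725) with the filter of 5 FPKM, and when a library was left out for NF-kB genes (0.588, 0.808 and 0.986, range 0.562 to 0.986), fatty acid synthesis (0.849, range 0.757 to 0.950), the unfolded protein response (0.771, range 0.355 to 0.897) and ribosomal proteins (0.664 and 0.886, range 0.164 to 0.886). The proliferation list reached 0.0446 without a filter, fatty acid oxidation 0.0309 without control replicate 2, ribosomal proteins 0.0313 and oxidative phosphorylation 0.0274 after quantile normalization, and mitochondrially encoded genes 0.0337 with the block.

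Log2 changes near 0 turned positive after quantile normalization for BAX (0.0070), RPL10 (0.0084) and CTNNB1 (0.0043), and in some leave-one-out fits, which ranged from -0.0901 to 0.0410 for BAX, -0.170 to 0.0852 for SAA1, -0.139 to 0.0734 for SAA2, -0.0366 to 0.0097 for RPL10 and -0.0544 to 0.0209 for CTNNB1. Over the named genes, alternatives that kept all libraries ended a call in 57 comparisons, 34 of them without a filter, and added 6. Leave-one-out fits ended 118 and added 1. Beyond the smaller samples and larger families, the cause was not tested. Depth is unknown, so the precision of low values cannot be given.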

Other observations

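The tests of the scaling offset, of S-phase genes, of overlapping neighbours and of the enterocyte, xenobiotic, histone and stress lists under other splits, and all lists and genes of this and the next paragraph, were chosen after the result was seen. These lists were picked after members were seen to move, so their counts are no test of a group change. Of 5 tested genes of the kallikrein cluster on chromosome 19, which encode secreted serine proteases, 3 rose and 0 fell. KLK6 went from 91.1 ± 16.8 to 262 ± 18.9 FPKM (limma adjusted p = 8.06e-04), KLK10 from 15.7 ± 3.21 to 41.7 ± 5.22 FPKM (adjusted p = 0.00176) and KLK7 from 4.75 ± 1.78 to 13.3 ± 2.19 FPKM (adjusted p = 0.0157), while KLK1 was at 26.7 ± 5.83 and 24.8 ± 1.84 FPKM (adjusted p = 0.832) and KLK8 at 0.861 ± 0.33 and 1.77 ± 0.782 FPKM (adjusted p = 0.236). In a list of brush border genes 7 of 14 tested rose and 0 fell, but USH1C, VIL1 and ESPN among the 7 also belong to the enterocyte list. PPP1R14D, also among the 7, belongs to the 12 largest rises, and its place at the brush border was not checked. EPS8L3 rose from 23.5 ± 2.50 to 61.6 ± 6.23 FPKM (adjusted p = 5.13e-04) and PDZK1, a scaffold of apical transporters, from 0.21 ± 0.0645 to 1.95 ± 0.548 FPKM (adjusted p = 0.00364), while EZR, the ezrin gene, was at 140 ± 6.41 and 141 ± 5.81 FPKM (adjusted p = 0.945). Of 9 tested complement genes C2, C3 and CD59 rose and 0 fell. C2 went from 0.286 ± 0.193 to 2.57 ± 0.569 FPKM (adjusted p = 0.00219) and CD59, an inhibitor of complement lysis, from 107 ± 2.29 to 126 ± 6.18 FPKM (adjusted p = 0.0355).

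Of 6 tested metallothionein genes, which encode metal-binding proteins, 3 fell and 0 rose. MT2A went from 1196 ± 53.8 to 829.6 ± 7.61 FPKM (adjusted p = 0.00143), MT1X from 94.8 ± 1.53 to 61.3 ± 5.57 FPKM (adjusted p = 0.00191) and MT1E from 83.9 ± 6.68 to 65.9 ± 4.21 FPKM (adjusted p = 0.0337), with MT1F at 15.7 ± 0.713 and 11.8 ± 2.00 FPKM (adjusted p = 0.0964). These genes are near-identical to one another, so fragments can be shared between them. Of 9 tested genes of the HOXB cluster 5 fell and 0 rose. HOXB2 (20.3 ± 2.19 to 12.04 ± 1.68 FPKM, adjusted p = 0.0102), HOXB4 (14.2 ± 0.974 to 10.7 ± 0.607 FPKM, adjusted p = 0.0269), HOXB5 (32.0 ± 2.09 to 24.8 ± 2.13 FPKM, adjusted p = 0.0371), HOXB8 (105 ± 2.70 to 80.3 ± 5.96 FPKM, adjusted p = 0.0113) and HOXB9 (25.6 ± 1.92 to 19.8 ± 1.63 FPKM, adjusted p = 0.0421) fell, while HOXB6 was at 99.4 ± 4.603 and 92.5 ± 5.62 FPKM (adjusted p = 0.423). The homeobox genes DLX3 (1.69 ± 0.26 to 3.62 ± 0.229 FPKM, adjusted p = 0.00545) and DLX4 (1.72 ± 0.127 to 3.88 ± 0.323 FPKM, adjusted p = 0.00256) rose. EPAS1, the gene of the hypoxia-inducible factor HIF-2 alpha, fell from 57.4 ± 2.14 to 31.3 ± 4.48 FPKM (adjusted p = 0.00246).

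Other splits of the 6 libraries into 3 and 3 gave at most 1 gene higher and 1 lower, against 480 and 196 in the real split. For each count 1 of the 10 splits, the real split, reached the real value. Gene lists past the threshold numbered 4 in the real split and up to 7 in the others, and 4 of the 10 splits gave at least 4. The camera adjusted p of the enterocyte list was 1.35e-07 in the real split and 0.0102 at the smallest elsewhere, and that of the xenobiotic list 0.00103 and 0.0377, each reached by 1 of the 10 splits. With an estimated correlation both lists lost their call in the real split (camera adjusted p = 0.227 each, unadjusted 0.0182 and 0.0153). The estimated correlation was 0.184 in the enterocyte list and -0.00184 in the xenobiotic list. As the latter is under the preset 0.01, a higher correlation is not the cause of the loss in the xenobiotic list. The version with an estimated correlation also tests with fewer degrees of freedom, those left by the few libraries. Neither loss therefore measures correlation alone. The camera adjusted p of the immediate early and stress list was 0.00977 in the real split and smaller in 3 others (0.00386, 0.00101 and 0.00648). That of the histone list was 8.82e-04 in the real split, and 3.01e-07, 0.00101, 0.0261 and 0.0377 in the others past the threshold. The 10 splits are too few for a share under 0.05. Each of the other splits also mixed libraries of the real groups. Part of the real difference then stayed between its groups, and the rest entered the spread within them. Low gene counts are likely in such splits, and their list values can carry part of the real difference, so they give no chance level.

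More genes were higher than lower in HNF4A overexpression. An offset between libraries left by the authors' scaling could give such an excess. After median-of-ratios scaling, with a largest factor shift of 0.0197 log2, 65.12 percent of calls were higher (95 percent binomial interval over genes 61.42 to 68.68). Called genes come from the same libraries and are not independent, so this interval is too narrow. The excess stayed after this scaling, which argues against the small offset it removed as the whole cause. An offset that this scaling does not detect stays open. With the replicate block 61.4 percent were higher. A biological effect of the added HNF4A stays open and was not tested.

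The replication-dependent histone list passed as lower by camera, but 0 of its 6 tested members passed, and the call was lost with an estimated correlation (adjusted p = 0.647), and fry did not pass (adjusted p = 0.366). Among all 33 tested histone genes of this kind, a wider set chosen after the result was seen, 30 had a negative log2 change and 2, HIST1H4H and HIST2H3D, passed (median -0.26, bootstrap 95 percent interval -0.44 to -0.14). Uneven recovery of non-polyadenylated RNA may lower histone values, if the histone transcripts measured here lack poly(A) tails. These values do not show whether they do. In the other direction, 12 non-polyadenylated RNAs other than histones had a median log2 change of 1.13 (0.22 to 1.29). Of these 2, RN7SK and SCARNA10, were past the threshold as higher and 2 were negative. Their values varied widely between libraries, and the interval is over genes and not libraries. In control replicates 1 to 3 RMRP, next to the median, was at 9.80, 7.57 and 0.0104 FPKM and RN7SL1 at 725, 143 and 197 FPKM. These RNAs therefore do not settle whether recovery was uneven. Fewer cells in S phase might also lower them, but 22 S-phase genes had a median of -0.0243 (-0.0539 to -0.00915), a smaller fall than that of the histone genes, which leaves a contribution of that size open. Fragments shared between near-identical histone genes were not tested, the histone list also passed in 4 of the other splits, and an effect of HNF4A stays open.

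Called genes were spread over the genome. A regional copy-number difference between the 2 cell populations could move runs of neighbours. Medians of windows of 51 tested genes ranged from -0.119 to 0.11, so none was shifted by over 0.2 log2. The share of called genes in such shifted windows was thus 0 percent whatever genes were called, and its 95 percent interval (up to 0.552) adds nothing. Differences over fewer genes, or in part of the cells, can escape such windows. The lowest window was centred on ABT1 on chromosome 6 (start 26596952), between the histone genes HIST1H1C and HIST1H2BK. The fall of histone genes and a shift of this region were not told apart. On a finer scale, 61 adjacent pairs were called in the same direction, against a median of 19 and a 95th percentile of 26 when calls were shuffled (permutation p = 0.0001, the smallest that 10000 shuffles can give), among them MX2, MX1 and TMPRSS2 on chromosome 21. Without overlapping genes 41 pairs were left, against 15 and 21 (permutation p = 0.0001), so fragments shared by overlapping genes may account for only part of the excess. Shared regulation of neighbours and the grouping of related genes in clusters stay open and were not tested.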
